A study of Mus musculus with 2 samples.

How the data were processed

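Gene expression was measured in skin of newborn mice that lack keratin 5 (K5 knockout) and in skin of wild type mice. Per the labels' protocols, the skin of 6 animals per group was snap-frozen, total RNA was isolated with TRIzol and pooled by group, and a column clean-up (RNeasy) ended the extraction. Biotinylated cRNA was made from 2 µg of total RNA. Each pool was read on 1 array, so the data hold 2 arrays in all. The labels name the tissue in different ways: the source name is epidermis, while the titles and the protocol speak of skin. It is called skin here, because the protocol describes no separation of the epidermis.

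The deposited values are intensities, 1 per probe set, on a linear scale. The submitters' processing notes name MAS5, the Affymetrix algorithm that combines the probes of a probe set into 1 signal. Its version, its scaling target and its detection calls were not given in the sources used here. The 2% trimmed mean over all probe sets was 1000.5 on the knockout array and 1000.6 on the wild type array, so the deposited intensities had been brought to a common level. The deposited values ran from 0.1 to 67511 on the knockout array, with a median of 437, and from 0.1 to 57173 on the wild type array, with a median of 402. MAS5 scales every array to 1 overall level, so a difference in total RNA per cell between the pools cannot be seen in these values.

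The table holds 12488 probe sets, of which 66 are controls. Of the other 12422, the platform annotation gives 1 gene symbol for 10833, several for 396 and none for 1193. Genes were named only from probe sets with 1 symbol. Entrez identifiers of 10839 single-symbol probe sets, controls included, were found in a RefSeq gene table of assembly GRCm38.p6, and 0 symbols needed an update. That table served for names and for which genes lie on the X chromosome. The platform annotation gives no coordinates, and none are printed.

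From the deposited intensities the following was computed. Each array was scaled to the same 2% trimmed mean over the non-control probe sets, with factors of 1.0001 and 0.9999. A floor was then set at the 40th percentile of all values, 246.7 signal units, because low MAS5 signals carry little information, and values below it were raised to it before log2 was taken. A gene with several probe sets was represented by the one with the highest mean. A gene counted as measured when it lay above the floor on at least 1 array. For a gene at the floor on 1 array the ratio is a lower bound and is written as at least that many fold. A gene at the floor on both arrays has no ratio.

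With 1 array per group there is no residual degree of freedom, so no test was run. Results are sizes: log2 ratios of knockout over wild type, and counts of genes that differed at least 2-fold. Each of 37 gene lists, fixed before the data were examined, is described by the median log2 ratio of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn from measured genes matched on mean level in 20 bins. A list was said to stand apart when the percentile was under 2.5 or over 97.5. Lists with fewer than 3 measured members received values only. These percentiles describe the 2 arrays and not the genotypes, and genes of a list are not independent of each other.

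The spread between probe sets of the same gene was the available measure of technical error. Over 838 genes with at least 2 probe sets above the floor on both arrays, its standard deviation was 0.30 on the log2 scale, with 0.33 for the dimmest group of genes and 0.23 for the brightest. It contains no variation between animals, pools or hybridisations. The number of arrays limits the precision of every value.

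The calculation was tested on simulated data made for the comparison of K5 knockout with wild type, with 5844 genes and a standard deviation of 0.25. All 100 genes altered 3-fold and all 100 altered 4-fold were called in the right direction (100% each), and 0% of 5644 unaltered genes were called. The altered genes were drawn only from genes far above the floor. The simulated standard deviation was below the 0.30 found between probe sets of the same gene, and it made calls of unaltered genes very unlikely by design. These shares therefore do not describe calls of dim genes. Of 200 unaltered lists of 20 genes, 7% stood apart, against the 5% that the percentile limits imply for lists without effect. Of 50 lists shifted by 0.3 on the log2 scale, 100% stood apart. The simulated noise was drawn separately for each probe set, with the same standard deviation of 0.25. The share of shifted lists therefore does not describe how often a real list with such a shift would stand apart.

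Genes were named by a rule written before the data were examined. It takes Krt5, Krt14, Il1b, Il6 and Tnf. It takes the 12 genes with the highest and the 12 with the lowest log2 ratio among genes above the floor on both arrays, leaving out genes with another probe set of opposite sign. Ifnar2 (log2 ratio -1.09) and Ttc39b (-1.08) had such probe sets. It takes the 6 brightest genes on each array that were at the floor on the other with a ratio of at least 2, and up to 4 measured members per list with the largest ratios. Fos, Egr1, Dusp1, Ccn2, Pcna, Hmgb2, Mki67, Il1a, Il18, Itga6, Krt15, Uty and Kdm5d were named in addition, after their values were seen, as were the genes of the closing observations that belong to no list.

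The alternatives chosen before the data were examined were the values as deposited, quantile normalization, a lowess correction with a span of 0.3, a median ratio set to 0, floors at the 25th and 60th percentiles, a pseudocount in place of a floor, the mean over probe sets, plain probe sets only (without suffixes that mark shared or less specific probes), thresholds of 3-fold and 1.5-fold, genes above the floor on both arrays only, 5 level bins, and the mean of a list in place of its median. Added after the data were seen were the ranks of Il1b, Il6 and Tnf among probe sets of like level without a floor (not reported, since these signals lie under the floor), list members above the floor on both arrays only, lists without the members they share with the immediate early genes, and a set of purine synthesis and salvage genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.

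Probe sequences were not used here. Members of close gene families, among them Hspa1a and Hspa1b, Krt6a and Krt6b, Krt16 and Krt17, the hair keratins and the Sprr genes, can share probes, and their single values are uncertain for that reason. Real-time PCR and ELISA, which the series' design text mentions, were not analysed here.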

Results

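The series asked which genes differ in the skin of mice without keratin 5, a model of epidermolysis bullosa simplex (EBS), and in particular whether inflammatory cytokines are among them. Keratin 5 pairs with keratin 14 in the basal layer of the epidermis, and EBS is a blistering disorder in which basal keratinocytes rupture. RNA of 6 newborn K5 knockout mice and of 6 newborn wild type mice was pooled by group, and each pool was read on 1 array. There are no replicates, so every value below compares these 2 arrays. Of 8251 genes with a probe set, 5976 were above the floor of 246.7 signal units on at least 1 array and 2275 were at the floor on both.

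In knockout skin, 92 genes were at least 2-fold higher and 42 were at least 2-fold lower than in wild type skin, together 2.24% of the measured genes. Genes with high ratios included immediate early genes, a heat shock gene, a chemokine gene and a wound keratin gene. Nr4a1, an immediate early nuclear receptor, was 5.43-fold higher, with signals of 4844 in the knockout and 892 in the wild type. Hspa1a, a heat-inducible chaperone, was 5.16-fold higher, the chemokine gene Cxcl1 4.59-fold and the wound keratin gene Krt16 4.58-fold. Among the lower genes were Gmnn and Mad2l1, which act in DNA replication and mitosis, and Krt12, the keratin of the corneal epithelium, had the lowest ratio among genes above the floor on both arrays, 4.04-fold lower (285 against 1150).

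The central 95% of measured genes had log2 ratios between -0.74 and 0.85, with a median of 0.04, and log2 signals correlated across probe sets above the floor on both arrays with r = 0.962, where genes are not independent replicates. Of the higher genes, 76 were above the floor on both arrays, and of the lower genes 36 were. With quantile normalization the split was 79 higher and 59 lower. Calls of dim genes depended on the treatment of low signals: of 77 named genes at least 2-fold different, 38 were under 2-fold with the floor at the 60th percentile and 33 with a pseudocount in place of a floor. Probe sets of the same gene were compared where at least 2 lay above the floor on both arrays. Among these genes, 12 had a brightest probe set that differed at least 2-fold. The second probe set had the same direction in 10 of them and was itself at least 2-fold different in that direction in 4.

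**Figure D1:**
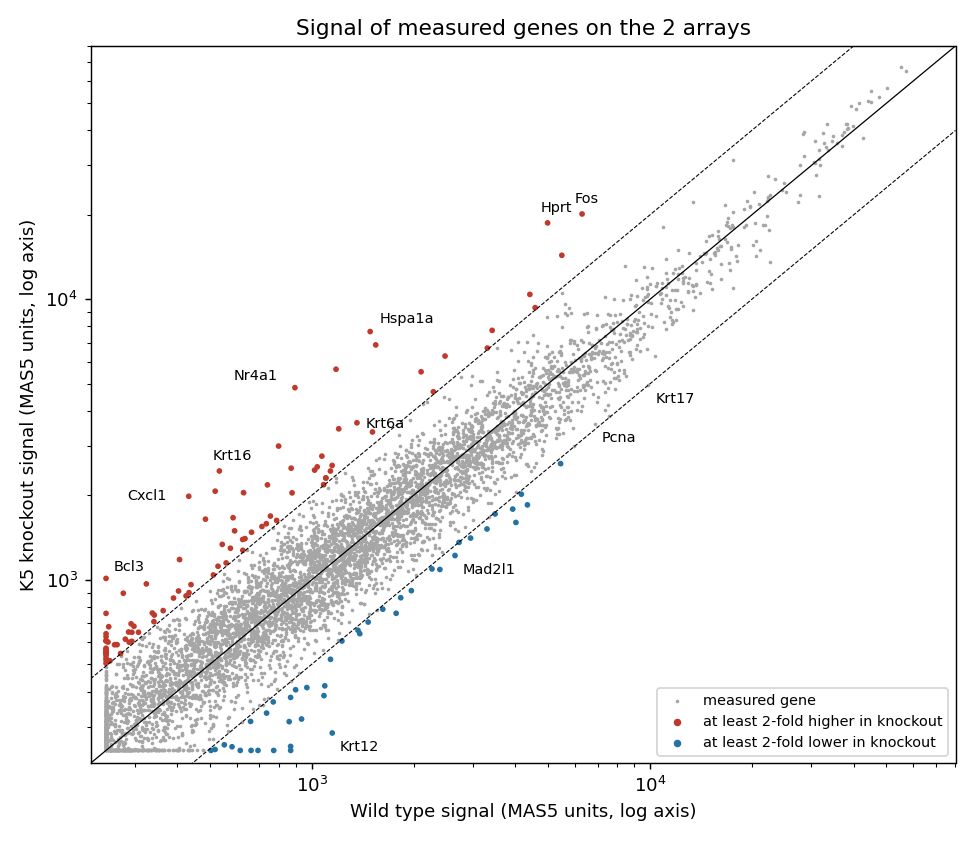
Signal of each measured gene on the wild type array (x axis) and on the K5 knockout array (y axis), in MAS5 units on log axes, with values below the floor drawn at it; the dashed lines mark a 2-fold difference. Most of the 5976 genes lie between the lines, with 92 genes above the upper line and 42 below the lower one.

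The other genes with the highest ratios among those above the floor on both arrays included several regulators of signalling and transcription. Zfp36, which encodes a protein that destabilises cytokine mRNAs, was 4.77-fold higher, Atf3, a stress-induced transcription factor, 4.45-fold, and Socs3, a feedback inhibitor of STAT3 signalling, 3.99-fold. Hprt, a purine salvage enzyme often used as a reference gene, was 3.76-fold higher (18728 against 4980). Fosb was 3.75-fold higher, Zfp638 3.39-fold, Prcc 3.25-fold and Elf3, an epithelial transcription factor, 3.23-fold. Of 302 genes above the floor in the knockout alone, the brightest with a difference of at least 2-fold were Bcl3, an NF-kB cofactor, at least 4.10-fold higher, and Sprr3, a cornified envelope precursor, at least 3.08-fold higher. They were followed by Zbtb17, Sstr2, Med1 and Gpr65, with bounds of 2.60, 2.54, 2.46 and 2.46-fold. Sstr2 was at the floor on both arrays when plain probe sets only were used. With the floor at the 60th percentile, Elf3 had a bound of 0.44, Bcl3 one of 0.62 and Sprr3 one of 0.20. Zbtb17, Sstr2, Med1 and Gpr65 were then at the floor on both arrays.

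After Krt12, the lowest log2 ratios among genes above the floor on both arrays were those of Smarcd1 (-1.76), a chromatin remodelling subunit, the transcription factor gene Irf4 (-1.55), Pmf1 (-1.49), which encodes a kinetochore protein, and Gmnn (-1.46), which encodes geminin, the inhibitor of replication licensing. E2f8 had a log2 ratio of -1.38, the linker histone gene H1f10 -1.33, and Lmo1, Hspbp1 and Txnrd3 -1.23 each. Rac3 was at -1.19 and 2700099C18Rik at -1.18. Of 156 genes above the floor in the wild type alone, 6 differed at least 2-fold. They were Prp2, at least 3.51-fold lower in the knockout, Ash2l (at least 3.13-fold), the Notch modifier gene Lfng (at least 2.81-fold), Prr5 (at least 2.68-fold), Kat2a (at least 2.49-fold) and Trip13 (at least 2.04-fold). The Prp2 difference is smaller as the mean over its probe sets, with a log2 ratio of -0.79. Of the genes of this paragraph, only H1f10, Lmo1 and Txnrd3 were at least 2-fold lower under every setting. The others were under 2-fold with the floor at the 60th percentile, among them Krt12 (a bound of -0.80), Smarcd1 (-0.39) and Gmnn (-0.38). Rac3, Kat2a and Trip13 were then at the floor on both arrays.

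The targeted gene could not be used to check the labels. Krt5 read 81.2 in the knockout and 46.6 in the wild type, and its partner Krt14 read 41.6 and 27.0, both far under the floor in a tissue where basal keratins are abundant. Krt15, the third basal keratin, read 7.20 and 12.9, so none of the 3 basal keratinocyte keratins was measured. Probe sets that do not report abundant transcripts occurred elsewhere on these arrays: of 26 ribosomal protein genes, 17 exceeded 20000 on both arrays while 5 were at the floor on both, with signals of at most 83.4. Whether the Krt5 probes lie in the deleted part is not known.

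Among the other keratins, the wound-associated genes Krt16 and Krt6a were higher in the knockout while Krt17 was lower. Krt16 was 4.58-fold higher (2445 against 534) and Krt6a 2.67-fold higher (3630 against 1361), and Krt6b had a log2 ratio of 0.50. Krt17, which is expressed in wounded epidermis and in hair follicles, read 4935 in the knockout and 9864 in the wild type, a log2 ratio of -0.999 that lies just short of the 2-fold threshold. The 4 stress and wound keratins had a median log2 ratio of 0.96, at percentile 99.98, with 3 higher and 1 lower. Hair follicle genes were higher on the same array, with a median of 0.48. The 4 measured suprabasal keratins had a median of -0.05 at percentile 36.7: Krt1 was at 0.28, Krt77 at a bound of 0.09, Krt10 at -0.18 and Krt2 at -0.51. Krt6a, Krt6b, Krt16 and Krt17 have close relatives, and their single values are uncertain.

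Chemokine and cytokine genes were higher as a group in knockout skin. Of 37 genes of the inflammatory cytokine and chemokine list on the array, 21 were at the floor on both arrays; among the 16 measured, 13 were higher and 3 were lower, 3 of them at least 2-fold higher and 0 at least 2-fold lower. The neutrophil attractant Cxcl1 was 4.59-fold higher (1986 against 433) and the monocyte attractant Ccl2 2.12-fold higher (1118 against 529), Ccl7 was at least 2.23-fold higher, and the macrophage growth factor gene Csf1 had a log2 ratio of 0.95. Of these 3, only Cxcl1 was at least 2-fold higher under every setting. Ccl2 had a log2 ratio of 0.997 with quantile normalization, 0.82 with a pseudocount in place of a floor and a bound of 0.76 with the floor at the 60th percentile; Ccl7 was at 0.84 with the pseudocount and at the floor on both arrays with the higher floor. Il18 had a log2 ratio of 0.43 and Il1a one of -0.14. The median of the list was 0.42, at percentile 99.6, against -0.13 to 0.35 for 95% of the random lists. The labels name cytokine induction as the study's outcome on these samples, so this list is not independent evidence of its direction. Macrophage and monocyte markers were higher on the same array, with a median of 0.25.

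Il1b and Il6, which the labels report as upregulated, were at the floor on both arrays, so no fold is given. Il1b read 156 in the knockout and 41.3 in the wild type, and Il6 read 212 and 63.1. Tnf read 43.5 and 33.0. The study picked Il1b and Il6 on these samples. With the floor at the 25th percentile Il1b was at least 1.79-fold and Il6 at least 2.43-fold higher.

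Genes of the IL-6 and STAT3 pathway were divided. Of 10 measured genes, 6 were higher and 4 lower, with Bcl3 at least 4.10-fold and Socs3 3.99-fold higher, Lbp at a log2 ratio of 0.87 and the receptor gene Lifr at -0.32. The median was 0.24, at percentile 91.5, which does not stand apart. The mean of the list, 0.51, did (percentile 99.9), as did the median with the floor at the 60th percentile (0.29, percentile 98.4). The median was smaller with quantile normalization (0.17, percentile 88.9) and with members above the floor on both arrays only (0.19, percentile 85.5). Of 8 measured IL-1 pathway genes, 3 were higher and 5 lower, with Myd88 at 0.49, Traf6 at 0.36, Irak1 at -0.31 and the receptor gene Il1r1 at -0.50. The median was -0.21, at percentile 5.80, and -0.28 at percentile 0.97 with the floor at the 25th percentile. It was smaller with the mean over probe sets (-0.05, percentile 25.02) and by the mean of the list (-0.0755, percentile 20.6).

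The labels state that TNF pathway genes were not involved. Of 20 measured genes of that pathway, 14 were higher and 6 lower in knockout skin, with 1 at least 2-fold higher: Lta, which encodes lymphotoxin alpha, 2.38-fold higher (697 against 293). Lta, a dim gene, was under 2-fold with a pseudocount in place of a floor (0.81) and with the floor at the 60th percentile (a bound of 0.08). Birc3, an inhibitor of cell death, was at a log2 ratio of 0.85, and the receptor adaptors Tradd and Traf2 were at 0.63 and 0.53. The median was 0.25 at percentile 96.0, inside the range of -0.10 to 0.26 for 95% of the random lists. Against the random lists of each setting, the list stood apart, at a median of 0.32, with the floor at the 60th percentile and with the mean over probe sets. It did so too, at 0.32, with plain probe sets only and with members above the floor on both arrays only. With the floor at the 25th percentile a median of 0.32 did not stand apart (percentile 95.8). The median was smaller with quantile normalization (0.14, percentile 92.3) and with the lowess correction (0.17, percentile 94.65). The difference between the TNF list and the cytokine list was not tested.

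NF-kB target genes were higher, 14 of 16 measured, with a median of 0.40 at percentile 99.9. The list stood apart under every alternative, but the size of its median depended on the setting, from 0.30 with quantile normalization to 0.84 with the floor at the 25th percentile (21 genes). With that floor Il1b and Il6, which the study picked on these samples, enter the list at bounds of 0.84 and 1.28. The list shares genes with the cytokine list, so it is not independent evidence either. The median of the macrophage and monocyte markers, 0.25, is to be set beside that of the NF-kB targets. Cxcl1 and Ccl2 belong to this list too, together with Gadd45b, a stress sensor gene at a log2 ratio of 1.34, and the survival gene Ier3 at 0.997. For Gadd45b the ratio was 0.29 from plain probe sets only. Without the members shared with the immediate early genes, the NF-kB list had a median of 0.34 at percentile 99.2. Interferon response genes did not stand apart (13 measured, median 0.13, percentile 63.3), although Irf1 was at 0.90 and Tap1 at -0.49. Alarmins and antimicrobial genes had a median of -0.02 (8 measured, percentile 32.0), with Lyz2 at 0.49 and the cathelicidin gene Camp at -0.84.

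Immediate early genes were higher in knockout skin as a group. Of 23 measured, 19 were higher and 12 at least 2-fold higher, with a median log2 ratio of 1.18 that exceeded the median of each of the 10000 random lists, 95% of which lay between -0.18 and 0.15. Besides Nr4a1, Zfp36, Atf3 and Fosb, the AP-1 gene Fos was 3.20-fold higher (20148 against 6299), Egr1 was 2.62-fold higher and the phosphatase gene Dusp1 2.62-fold higher. Ccn2, a YAP target that encodes a matricellular protein, was the lowest member at -0.74. The 3 prime over 5 prime signal ratios, a sign of RNA integrity, were 1.04 in the knockout and 1.06 in the wild type for Actb, and 0.841 and 0.831 for Gapdh.

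Heat shock and unfolded protein response genes did not stand apart as a group: 13 of 24 were higher, with a median of 0.04 at percentile 76.6. The inducible Hsp70 genes were the exceptions, Hspa1a at 5.16-fold and Hspa1b at 2.53-fold higher, while Dnajb9, a chaperone of the endoplasmic reticulum, was at -0.75 (-0.30 as the mean over probe sets) and Trib3 at 0.60. Hspa1a and Hspa1b are near-identical and may not be separable by probe. Apoptosis and p53 target genes had a median of 0.15 (16 measured, percentile 88.2), with Plk2 at 0.79 and the cell cycle inhibitor gene Cdkn1a at 0.73. Hypoxia and glycolysis genes had a median of -0.04 (22 measured, percentile 34.8): the secreted factors Adm and Vegfa were 2.98-fold and 2.71-fold higher, the hexokinase gene Hk2 was at 0.75, and Pgk1, a glycolytic enzyme gene, was at -0.51.

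**Figure D2:**
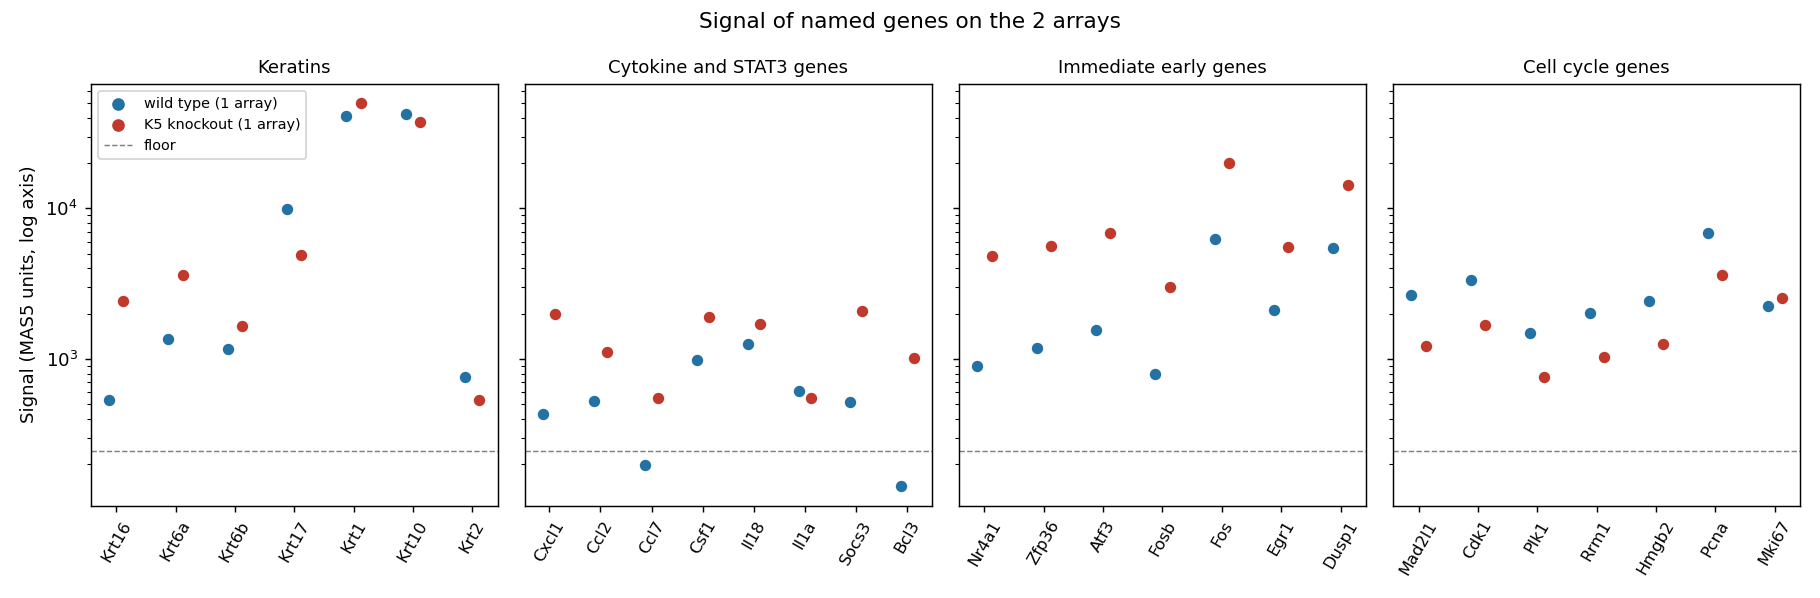
MAS5 signal of selected genes on the wild type array (blue) and the K5 knockout array (red), 1 point per array on a log axis, with the floor as a dashed line; panels show keratins, cytokine and STAT3 genes, immediate early genes and cell cycle genes. Krt16 was 2445 in the knockout and 534 in the wild type, while Pcna was 3594 and 6866.

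Proliferation genes were lower in knockout skin. Of 43 measured members of the cell cycle list, 38 were lower and 5 higher, with a median log2 ratio of -0.52 at percentile 0.0, against -0.11 to 0.16 for 95% of the random lists. The spindle checkpoint gene Mad2l1 was 2.17-fold lower (1221 against 2653) and was the 1 member past the 2-fold threshold. Cdk1, the kinase that drives entry into mitosis, was at -0.996, the mitotic kinase gene Plk1 at -0.97, Rrm1, a ribonucleotide reductase subunit, at -0.97, Hmgb2 at -0.95 and the replication clamp gene Pcna at -0.93. The widely used proliferation marker Mki67 did not follow, at 0.17 (2539 against 2255). Dermal and muscle markers were higher on the same array, with medians of 0.23 and 0.26, while desmosome and junction genes had a median of -0.05.

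Oxidative phosphorylation genes were lower as well, by less per gene. Of 41 measured, 35 were lower and 6 higher, with a median of -0.34 at percentile 0.0 and 0 members past 2-fold. Cycs, which encodes cytochrome c, was at -0.98, the complex I subunit genes Ndufc1 and Ndufv2 at -0.74 and -0.68, and the ATP synthase subunit gene Atp5o at -0.59. Markers of several tissues were higher on the same array, with medians of 0.48 for hair follicle, 0.26 for skeletal muscle, 0.25 for macrophages and 0.23 for dermal matrix, so a different tissue makeup of the 2 pools is not excluded. Ribosomal protein genes did not stand apart (21 measured, median 0.07, percentile 91.6), with Rps29 at 0.54 and Rps27 at 0.44.

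In the main setting, none of the lists of epidermal barrier and adhesion genes stood apart. Of 20 measured cornified envelope genes 16 were higher, with a median of 0.15 at percentile 96.8: Sprr3 was at least 3.08-fold higher, involucrin (Ivl) 2.41-fold (2462 against 1020), Sprr1a 2.05-fold and Rptn at 0.86. That list stood apart under 7 of the alternatives, with values from 0.15 with a pseudocount in place of a floor (percentile 98.4) to 0.40 with plain probe sets only (percentile 99.95, 12 genes). Epidermal lipid barrier genes had a median of 0.09 (14 measured, percentile 86.8), with the desaturase gene Scd1 at -0.85 and Sptlc2 at 0.29. Hemidesmosome and basement membrane genes had a median of 0.03 (15 measured, 8 higher, percentile 59.5), yet the laminin genes Lamb3 and Lama5 were at -0.71 and -0.63, the integrin genes Itgb4 and Itga6 at -0.56 and -0.38, and perlecan (Hspg2) at 0.61. As the mean over probe sets Lamb3 was at -1.04, and Lama5 lay between -0.66 and -0.40 over the settings. Desmosome and junction genes had a median of -0.05 (20 measured, 8 higher, percentile 35.9), with Dsc1 at 0.49 and Cldn1 at -0.39.

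Acute wound and matrix remodelling genes were higher in 12 of 15 measured, with a median of 0.30 at percentile 97.4, just inside the limits. Dermal matrix genes and macrophage markers were higher on the same array, with medians of 0.23 and 0.25. Vegfa was 2.71-fold higher, the EGF-family growth factor gene Hbegf at 0.91, and Plat and Plaur, of the plasminogen system, at 0.89 and 0.83. Vegfa was under 2-fold with a pseudocount in place of a floor (0.90) and had a bound of 0.05 with the floor at the 60th percentile, where Hbegf had a bound of 0.02, Plaur was at the floor on both arrays and Plat stayed at 0.89. This list stood apart with quantile normalization (0.31, percentile 99.0) and under 5 other alternatives, but its median was 0.05 at percentile 73.8 with the floor at the 60th percentile.

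Markers of other cell types of the skin were also compared, because a whole piece of skin holds follicles, dermis, muscle and blood cells. Hair follicle genes were higher, 21 of 22 measured, with a median of 0.48 that exceeded those of the 10000 random lists, among them the hair keratin gene Krt86 at 1.22, the keratin-associated genes Krtap3-1 and Krtap8-1 at 1.15 and 1.04, and Krt34 at a bound of 0.99; these belong to families with shared probes. With quantile normalization Krtap8-1 was at 0.96. Dermal fibroblast and matrix genes were higher in 26 of 34, with a median of 0.23 that also exceeded those of the 10000 random lists: tenascin X (Tnxb) was at 1.15, the fibroblast receptor gene Pdgfra at 1.02, Loxl1 at 0.85 and elastin (Eln) at 0.72. Skeletal muscle genes were higher in 33 of 40, with a median of 0.26 at percentile 99.99, led by the myosin genes Myh7 (1.18), Myh8 (0.94) and Myh1 (0.88). The probe sets of Myh7 and Myh8 carry suffixes that mark shared or less specific probes. Myh7 was at 0.83 with a pseudocount in place of a floor and had a bound of 0.47 with the floor at the 60th percentile. With plain probe sets only the muscle list still stood apart (0.22, percentile 99.5). For Pdgfra the mean over probe sets was 0.68.

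Macrophage and monocyte markers were higher in 16 of 20, with a median of 0.25 at percentile 99.4, among them Adgre1 (F4/80) at 0.97, the complement gene C1qb at 0.96 and the mannose receptor gene Mrc1 at 0.67, with Ctsz at -0.73. As the mean over its 2 probe sets C1qb was at -0.02. Its rise thus rests on 1 probe set, and the other was lower in the knockout. Adgre1, a dim gene, read 535 in the knockout and 273 in the wild type. Both signals lie under the floor at the 60th percentile (659.7 units). Neutrophil markers did not stand apart (9 measured, median 0.03, percentile 32.2; Csf3r at 0.40), nor did mast cell markers (9 measured, median -0.00, percentile 47.3; Mcpt1 at -0.54), Langerhans cell and MHC class II genes (10 measured, median -0.07, percentile 9.78; Epcam at -0.69) or T and B lymphocyte markers (4 measured, median 0.08, percentile 44.7; Cd4 at 0.18).

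The medians of the other tissue lists stayed within the random range. Endothelial markers had a median of 0.22 (16 measured, percentile 93.7), with Vwf 2.08-fold higher and the VEGF receptor gene Kdr at 0.77. With quantile normalization Vwf was at 0.92, and the mean of the endothelial list, 0.28, stood apart at percentile 98.1. Erythroid and blood markers had a median of 0.26 (7 measured, percentile 94.9; Alas2 at 0.40), and cartilage and bone markers one of 0.16 (7 measured, percentile 80.6; Col9a1 at 0.57). Adipocyte markers had a median of -0.06 (17 measured, percentile 20.3), although leptin (Lep) was 2.88-fold higher (2501 against 870). Melanocyte markers had a median of -0.02 (6 measured, percentile 39.5; Dct at -0.17), and nerve and Schwann cell markers one of -0.17 (9 measured, percentile 9.99; Gap43 at -0.46).

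**Figure D3:**
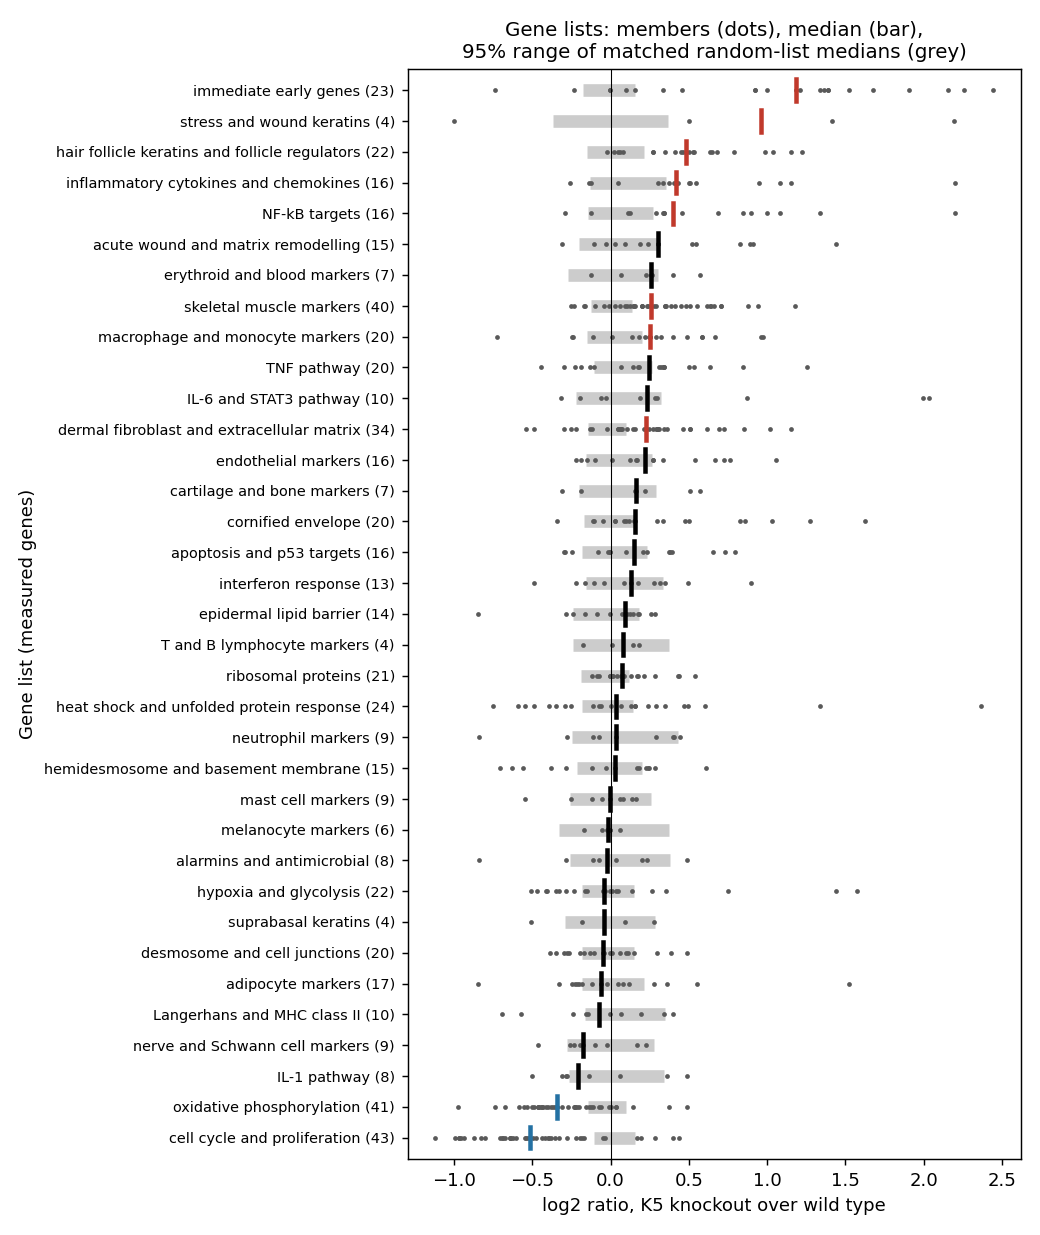
Log2 ratio of K5 knockout over wild type for the measured members of each gene list (dots), the list median (bar; red or blue where the list stands apart higher or lower, black otherwise) and the 95% range of medians of 10000 level-matched random lists (grey). Of 35 lists, 8 lie above that range, among them the immediate early genes at 1.18, and 2 lie below it, oxidative phosphorylation at -0.34 and the cell cycle at -0.52.

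Of 35 lists with a percentile, 8 stood apart as higher and 2 as lower, where 1.75 would if each list were drawn gene by gene at random. Genes of a list can vary together between any 2 pools, which random lists leave out, and several lists share genes. The count is therefore no measure of an effect of the genotype. Sex-linked genes differed between the pools: the Y-linked gene Eif2s3y read 1182 in the knockout and 407 in the wild type, a log2 ratio of 1.54, and Xist, which is expressed from the inactive X chromosome, read 64.3 and 294. Uty and Kdm5d, also Y-linked, were at the floor on both arrays, so this list of 2 measured genes received no percentile. Xist was at the floor in the knockout, with a bound of -0.25. With 1 pool per group, a different sex makeup of the pools cannot be told apart from the genotype. A standard deviation of 0.30 on the log2 scale between probe sets of the same gene sets the scale for single-gene ratios, and differences between animals are not contained in it.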

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

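No test was run in this part; its values come from probe sets that the report's comparisons leave out, and they were looked at after the report's results were known. Among 725 measured probe sets with no gene symbol or with several, 13 were at least 2-fold higher on the knockout array and 6 at least 2-fold lower. Among those above the floor on both arrays, the highest ratio was that of probe set 102348_at, which the annotation used here leaves unnamed, with a log2 ratio of 2.08 (1675 in the knockout and 396 in the wild type). Among the 6 lower ones was a probe set shared by Tyms, a gene of thymidylate synthesis, and its pseudogene Tyms-ps, with a log2 ratio of -1.08.

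The poly-A control probe sets, which report bacterial transcripts and are not used in any comparison, read higher on the knockout array in 12 of 12 cases, with a median ratio of 1.40 and a range of 1.05 to 1.73. The hybridisation controls, which by the usual protocol are added just before hybridisation, were higher in 9 of 9 cases, with a median ratio of 1.13 and a range of 1.01 to 1.495. The sources used here do not say how either control was added in this study.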

How the results depend on the processing

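The setting that keeps members above the floor on both arrays only and the one that leaves out members of the immediate early genes were chosen after the data were seen, and the others before. The 10 lists that stood apart did so under every alternative run for them, with medians of -0.55 to -0.38 for the cell cycle, -0.38 to -0.28 for oxidative phosphorylation, 0.92 to 1.18 for the immediate early genes and 0.34 to 0.60 for the cytokines. Of 421 list values under alternatives, 400 kept their side of the limits, 21 passed a limit that the main value had not, and 0 lost one; 29 of 35 lists had the same call throughout. Of 1814 single-gene values, 1663 moved by less than the spread between probe sets and 151 by more; 7, of 4 genes, had the opposite sign (Tyrp1, Ms4a1 and Ighm near 0, and C1qb), 0 of them among the genes at least 2-fold different. Of 77 named genes at least 2-fold different, 38 were under 2-fold with the floor at the 60th percentile, 33 with a pseudocount in place of a floor and at most 6 under any other setting. With the floor at the 25th percentile (86.9 units), 205 genes were at least 2-fold higher and 94 lower, Il1b had a bound of 0.84 and Il6 one of 1.28, and the IL-1 list stood apart at -0.28. With the floor at the 60th percentile (659.7 units), 44 genes were higher and 19 lower, the IL-6 and STAT3 list stood apart at 0.29 and the TNF list at 0.32. With a pseudocount in place of a floor the counts were 39 and 15, with Il1b at 0.48 and Il6 at 0.56, from signals under the main floor on both arrays and so not measured ratios. The TNF list also stood apart at 0.32 with the mean over probe sets, with plain probe sets only and with members above the floor on both arrays only, and the IL-6 and STAT3 list at 0.51 by the mean of the list. A 3-fold threshold gave 15 higher and 4 lower genes and a 1.5-fold threshold 456 and 315. Higher floors and the pseudocount compress ratios of dim genes by construction; the cause of the other differences was not tested. No scaling moved the median of all genes to more than 0.04 from 0. Signal over background limits dim genes, among them 21 of the 37 cytokine genes, which were at the floor on both arrays. No paired analysis was possible because each group has 1 array.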

Other observations

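Of the tests in this part, those on the keratinocyte share, on RNA integrity, on handling and on X dose were chosen only after the results they bear on were seen; the purine gene set and the minigene test were added after the Hprt value was seen. The genes of the first 2 paragraphs were picked because of their ratios, so they show nothing about other genes of the same functions. Several replication and mitosis genes outside the fixed lists were among the lower genes. The flap endonuclease gene Fen1 had a log2 ratio of -1.14, Cks2, a partner of cyclin-dependent kinases, one of -1.14, Dtl one of -1.07, the single-strand binding protein genes Rpa1 and Rpa3 -1.07 and -1.05, the condensin gene Smc2 -1.05, Pclaf, whose product binds the replication clamp, -1.02, and the licensing factor gene Cdt1 -1.003. With a pseudocount in place of a floor, only Cks2 of these genes stayed at least 2-fold lower. With the floor at the 60th percentile Fen1 had a bound of -0.44 and Dtl one of -0.22. Among single genes of other functions, the activin antagonist gene Fst was at -1.02, and the Notch ligand gene Jag2 (-0.99) and Wnt6 (-0.96) lay just short of the 2-fold threshold.

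Single genes outside the lists were also higher. Serpinb2, an inhibitor of plasminogen activators, was 2.36-fold higher (10412 against 4415), tissue factor (F3) 2.04-fold higher (9339 against 4576) and Procr, the receptor of protein C, 2.06-fold higher. Krt4, a keratin of mucosal epithelium, was 2.23-fold higher and Plet1 2.23-fold higher. The antioxidant regulator Nfe2l2 was 2.04-fold higher, the extracellular peroxidase Gpx3 2.95-fold higher, the pattern recognition gene Ptx3 2.29-fold higher, and Cish, a feedback inhibitor of STAT signalling, had a log2 ratio of 0.999. Of these genes, only Serpinb2, Plet1 and Gpx3 were at least 2-fold higher under every setting. Procr, with a wild type signal of 248 just above the floor, was at 0.91 with quantile normalization, and Nfe2l2 at 0.96. With the floor at the 60th percentile Procr was at the floor on both arrays and Ptx3 had a bound of 0.05. Krt4 and F3 were under 2-fold with a pseudocount in place of a floor (0.91 and 0.99).

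The lower cell cycle list (median -0.52) may reflect fewer dividing cells in knockout skin, a hypothesis found on these data that no test here decides. Mki67 (0.17) and 4 other members of the list were higher in the knockout. A lower share of keratinocytes in the knockout skin would lower keratinocyte genes in general, but the desmosome and junction list had a median of -0.0466 over 20 genes. That list cannot exclude a lower share, since some of its genes, such as Ctnnb1 and Tjp1, are not particular to keratinocytes. It also holds no basal keratin, and these were not measured. A trend of the log2 ratio with signal level is argued against by the lowess correction, after which the cell cycle median was -0.51. A smaller share of one dividing cell type, such as follicle matrix or basal cells, was not tested. The hair follicle list was higher in the knockout, with a median of 0.48 and 21 of 22 measured genes higher. No second pool shows how much the cell cycle list varies between litters.

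The higher immediate early genes (median 1.18) are a candidate trace of tissue damage, but these genes also respond to handling within minutes. More degraded RNA in 1 of the pools is argued against by the 3 prime over 5 prime ratios, which differed between arrays by a factor of 0.974 for Actb and 1.01 for Gapdh. More handling or a longer time before freezing in 1 pool cannot be told apart from the genotype: 12 of 23 members were at least 2-fold higher, and the design holds no second, separately handled pool.

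The higher Hprt signal (log2 ratio 1.91) was the highest among 172 measured X-linked genes (rank 1, with genes at the floor on 1 array taken at their bound), and the central 95% of the others lay between -0.74 and 0.67. A higher X dose from a different sex makeup of the 2 pools is argued against by size, since an all-female and an all-male pool differ at most 2-fold in X dose and Hprt exceeded that by more than the spread between probe sets (1.91 on the log2 scale). The Y-linked gene Eif2s3y, at 1182 in the knockout and 407 in the wild type, argues against a higher X dose by direction. It rests on 1 probe set, whose suffix marks shared or less specific probes. Xist, a dim gene, read 64.3 and 294, and its bound of -0.25 is smaller than the spread of 0.30 between probe sets. By Eif2s3y the knockout pool held less female RNA, and Xist alone does not decide it. The median of the other 171 X-linked genes, -0.02, decides nothing here, since X inactivation levels most of them between the sexes. A joint rise of purine synthesis and salvage genes is argued against by a median of 0.0554 over 14 such genes, from -0.48 for Adsl to 0.45 for Xdh. A candidate explanation is an Hprt minigene as the selection marker of the targeted allele, a marker in use in mouse gene targeting; Hprt's own ratio was known when the rank was computed and no construct sequence was used here, so it stays open beside an effect of the genotype.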
